A study of Mus musculus with 7 samples.

How the data were processed

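RNA was sequenced from the tissue around the brain ventricles of adult mice of the Dcdc2a-TRAP line ES2575. TRAP (translating ribosome affinity purification) uses a transgene that adds EGFP to the ribosomal protein Rpl10a in chosen cells, here under the control of Dcdc2a. Polysomes carrying the tag are pulled from the homogenate with antibodies to EGFP on magnetic beads. The labels give 3 libraries of immunopurified RNA (IP, numbered 1, 3 and 4) and 4 libraries of total RNA from the same kind of homogenate (Input, numbered 1 to 4). An IP numbered 2 was not analysed here.

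The deposited tables hold whole-number counts per gene symbol, 1 table per library, and the authors gave no normalisation. Per the submitters' processing notes, STAR 2.0.0e and HTSeq were used with the mouse genome build mm10. Their settings, the gene annotation, the treatment of strand and the library kit are not given in the sources used here. Each table also gives totals for reads in no gene, in more than 1 gene, or aligned to more than 1 place. These lines stayed out of library sizes and tests, and together made up 40.1% to 52.1% of all lines per library. Reads aligned to more than 1 place were not counted to genes, so genes with near-identical copies have low counts. Where genes overlap or lie antisense to each other, their reads cannot be assigned with certainty because the strand setting is unknown. Besides the genes marked for this below, Rpl10a, Cluap1, Dio2, Csf1r, Slc2a1, Neat1 and Igf2 overlap other models and are uncertain.

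Counts assigned to genes ranged from 37203427 (Input 3) to 52175180 (IP 1). At this depth 3 counts in a library correspond to between 0.0585 and 0.0819 counts-per-million (CPM), counting error only. The tables list 32531 symbols. Of these, 23113 matched a single gene of GENCODE release M21 by symbol and 770 through a RefSeq synonym, 44 matched several genes and 8604 none. Of the tested genes 90.1% were matched. Positions are given from that release, which uses the same assembly as mm10, 1-based.

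Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total count 15), which left 17375. Libraries were scaled with TMM factors. IP was compared with Input over all 7 libraries with edgeR's quasi-likelihood test (glmQLFit with robust moderation, glmQLFTest) and group as the only term. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. An adjusted p from this test is called the edgeR adjusted p. Standard errors (SE) of log2 fold changes were taken as the fold divided by the square root of the test statistic. CPM values are on the TMM scale and are given as mean ± SD. A ratio of a single library to the mean Input is on the log2 CPM scale with a prior count of 2.

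The 29 gene lists (cilium parts, cell type markers, pathways) were fixed before the data were examined. The mitochondrially encoded list had no symbol in the tables and was not analysed here, which left 28. They were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was repeated with a correlation estimated from the libraries, under which 0 of the 28 lists passed. At an unadjusted p under 0.05, 5 lists were higher and 0 lower with the estimated correlation. The fry test, which asks whether the genes of a list move one way on balance and compares no lists, called 15 lists. The list of lncRNAs and that of neurons share Snhg11, and the ribosomal protein and doublecortin lists hold Rpl10a and Dcdc2a, which were also named on their own.

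Genes named in the text followed a rule fixed before the data were examined. It took Dcdc2a, Rpl10a, Foxj1 and Ttr always. It took the 10 genes with the largest positive and the 10 with the largest negative log2 fold among called genes with a mean CPM of at least 5 and no overlap between IP and Input libraries. It took the 2 members of each list with the smallest p, and a list's strongest called member against its majority. A gene that the rule takes is not reported here. Models without a proper name were skipped, and names that are sequence accessions were counted among these. Other genes named are said to be chosen after their values were seen, and further members named as examples of a list's called genes were also chosen afterwards.

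The replicate numbers were treated as pairing the libraries, because the labels place the IP and the Input of each number on the same sequencing lane (numbers 1, 3 and 4 on lanes 4, 2 and 3) with neighbouring library numbers. Whether a number also marks an animal is not labelled. The deviations of same-numbered libraries from their group means had correlations across genes of 0.032, 0.043 and 0.026, each the highest of that IP with any Input. Genes are not independent replicates. The fit with the replicate number as a block is given beside results whose call it changes. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No library was a copy of another: every pair of libraries of a group differed by more than sampling noise in at least 12905 genes (chi-square test of counts, Benjamini-Hochberg adjusted).

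The test was tried on simulated counts with the means and library sizes of the 7 libraries, for IP against Input over 17043 genes. It called 10.4% of genes changed 2-fold, 65.7% of those changed 4-fold and 90.9% of those changed 8-fold, and 3 of 16843 unchanged genes. A list raised 2-fold was called by camera (adjusted p = 6.56e-20, and 0.00326 with an estimated correlation), with 0 of the other lists called. The simulated genes were drawn independently of each other, and no library was made to deviate from its group. In the data the estimated correlation within a list reached 0.86 (blood cells). The simulation therefore does not show how often lists or genes are called falsely in these libraries.

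The alternatives were DESeq2 size factors, total counts, upper quartile factors and library sizes without the most abundant genes. They also included no low-count filter, a filter of CPM of at least 1, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, the replicate block, and offsets for GC content and transcript length with and without the block. Further fits used the series of the library number (838 to 843 against 924 and 925) as a covariate, or the lower-numbered libraries alone, and left out each library in turn. After the data were examined, the fits without IP 1 were repeated with the block and with an estimated correlation, and the main test without robust moderation.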

Results

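Ependymal cells line the ventricles of the brain and carry motile cilia. The libraries compare RNA bound to tagged ribosomes in the Dcdc2a-TRAP line (IP, 3 libraries) with total RNA of the tissue around the ventricles (Input, 4 libraries). The series, per its labels, profiles the ependymal cells of this line. Counts assigned to genes were 52175180, 42422439 and 50067661 in IP 1, IP 3 and IP 4, and 40826016, 44754345, 37203427 and 42140646 in Inputs 1 to 4.

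The gene that drives the tag, Dcdc2a (ENSMUSG00000035910.15, chromosome 13, 25056004 to 25210706, plus strand), had 210 ± 186 CPM in IP (SD, n = 3) and 45.3 ± 20.2 in Input (SD, n = 4). Its log2 fold of 2.21 ± 0.63 (SE) did not pass the test (edgeR adjusted p = 0.0743). IP 1 held 43.6 CPM, within the Input range of 27.7 to 73.9, against 411 in IP 3 and 175 in IP 4. Against the Input of the same number, the log2 ratios were 0.65 in IP 1, 2.48 in IP 3 and 1.98 in IP 4. Without IP 1 the gene was called, with a log2 fold of 2.69 (edgeR adjusted p = 0.00205). Foxj1, the transcription factor that drives the motile cilium programme (ENSMUSG00000034227.7, chromosome 11, 116330704 to 116335399, minus strand), rose from 8.22 ± 3.80 to 268 ± 208 CPM, a log2 fold of 5.03 ± 0.78 (SE, edgeR adjusted p = 0.0147). All 3 IP libraries (32.2, 345 and 427 CPM in IP 1, IP 3 and IP 4) were above every Input. With the replicate block the Foxj1 call was lost (log2 fold 4.41, edgeR adjusted p = 0.129), and it was lost without IP 4 or any 1 of the Inputs. Rpl10a, the ribosomal protein that carries the tag, had 5.54 ± 1.60 CPM in IP and 5.21 ± 2.21 in Input (log2 fold 0.09, edgeR adjusted p = 0.943). Reads of Rpl10a shared with copies elsewhere in the genome were not counted, so its level is uncertain. Ttr, the transthyretin gene that marks choroid plexus, had 2187 ± 928 CPM in IP and 2918 ± 734 in Input (log2 fold -0.42 ± 0.32, edgeR adjusted p = 0.493).

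**Figure D1:**
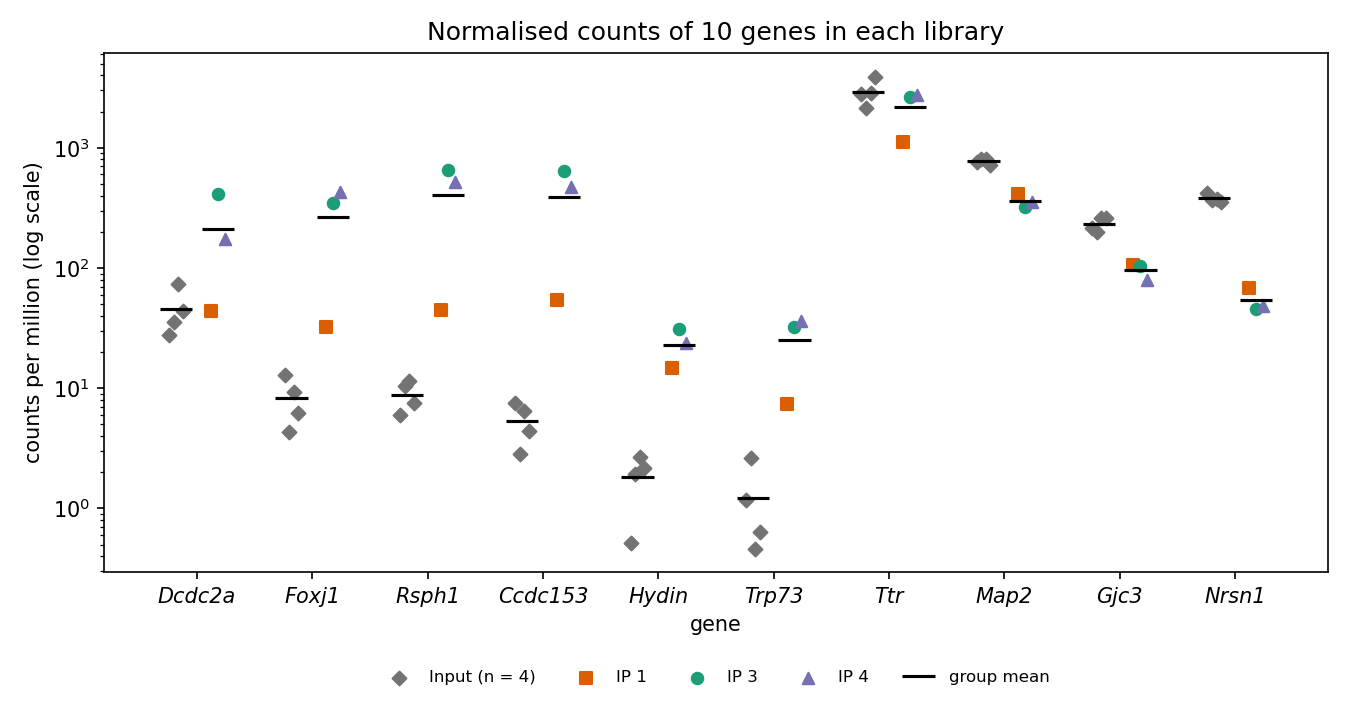
CPM of 10 genes in each library, on a log scale, with grey diamonds for the 4 Inputs, coloured symbols for the 3 IP libraries and bars for group means. Foxj1, Rsph1, Ccdc153, Hydin and Trp73 lie above every Input in all 3 IP libraries, with IP 1 the nearest to Input, and Map2, Gjc3 and Nrsn1 lie below every Input.

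Across the genome 633 genes were higher and 376 lower in IP among 17375 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). Of these, 604 were higher and 258 lower by at least 2-fold. The genes with the largest rise under the naming rule were Ccdc121, Dthd1, Fam216b, Lrrc18, Crygn, Dnaaf1, Rassf9, Ppp1r32, Tctex1d4 and Rarres2, with log2 folds from 6.25 (Rarres2) to 7.81 (Ccdc121). Dnaaf1 is a factor for assembly of axonemal dyneins, Tctex1d4 a dynein light chain relative, and Rarres2 encodes the chemokine-like protein chemerin. Ccdc121 rose from 0.203 ± 0.145 to 45.3 ± 37.2 CPM (log2 fold 7.81 ± 1.15 SE, edgeR adjusted p = 0.0129), and Fam216b from 2.11 ± 1.53 to 271 ± 219 CPM (log2 fold 7.01 ± 1.11 SE, edgeR adjusted p = 0.0147). Fam216b overlaps the antisense model Gm19301, Dnaaf1 overlaps Taf1c, Tctex1d4 overlaps Plk3 and Rarres2 overlaps Lrrc61, so these counts are uncertain. All 376 lower genes were below every Input in all 3 IP libraries. Of the 633 higher genes 547 were above every Input. Of the 28 gene lists 14 were called higher and 6 lower by camera, and 0 with an estimated correlation (5 higher and 0 lower at an unadjusted p under 0.05). Of all tested genes 9.55% had every IP above every Input, and 10.4% every IP below, where chance gives 2.86% each.

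The size of these counts depended strongly on single libraries and on the block. With the replicate number as a block 96 genes were higher and 33 lower, of which 80 and 32 were among those above; Fam216b (adjusted p = 0.000674), Dthd1 (0.0183), Rarres2 (0.0169), Tctex1d4 (0.0128), Crygn (0.0344), Lrrc18 (0.0372) and Dnaaf1 (0.0486) remained called by edgeR, and Ccdc121 (0.0987), Rassf9 (0.0922) and Ppp1r32 (0.129) did not. Without IP 1, 2259 genes were higher and 1724 lower. Without Input 1, Input 2, Input 3, Input 4 or IP 4, the higher genes numbered 21, 12, 4, 4 and 10, and the lower 30, 24, 16, 19 and 19. Without IP 3 they numbered 343 and 357. Within lanes, the genes called higher were above the Input of their lane in 606 of 633 cases on lane 4 (number 1, median log2 ratio 1.30), in 633 on lane 2 (number 3, 3.56) and in 633 on lane 3 (number 4, 3.27). The genes called lower were below it in 376 of 376 cases on each of these lanes, with medians of -1.22, -1.15 and -1.22. For the lower genes this follows from all of them lying below every Input. Both sets were called from these same libraries, so the counts within lanes add no support.

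Many genes for the structure and assembly of the motile cilium were higher in IP, though not all passed. Of 39 measured proteins of the cilium's doublets and related structures, 29 were higher and the others did not pass, with a median log2 fold of 4.16 (37 adjusted over the list alone; camera adjusted p = 4.79e-18, adjusted p = 0.251 with an estimated correlation). Cfap44, a motile cilium protein, rose from 8.10 ± 1.61 to 48.8 ± 20.8 CPM (log2 fold 2.59 ± 0.36 SE, edgeR adjusted p = 0.011), and Kif9, a kinesin, by a log2 fold of 2.71 ± 0.42 (edgeR adjusted p = 0.0129). Of 22 radial spoke and central pair genes 15 were higher (18 adjusted over the list alone; median 3.05; camera adjusted p = 1.76e-11, adjusted p = 0.242 with an estimated correlation). Rsph1, a radial spoke head protein, rose from 8.86 ± 2.52 to 404 ± 318 CPM (log2 fold 5.51 ± 0.77 SE, edgeR adjusted p = 0.0129), and Hydin, of the central pair, from 1.83 ± 0.93 to 23.1 ± 8.09 CPM (log2 fold 3.66 ± 0.55 SE, edgeR adjusted p = 0.0129). Of 20 dynein assembly and docking factors 10 were higher, among them Ccdc40 (log2 fold 4.24 ± 0.60 SE, edgeR adjusted p = 0.0117) and Dnaaf1 (log2 fold 6.43 ± 0.94 SE, edgeR adjusted p = 0.0129). For this list 17 passed adjusted over the list alone (median 2.50; camera adjusted p = 3.65e-11, adjusted p = 0.242 with an estimated correlation). Of 18 axonemal dynein chains 7 were higher, with Wdr63 at 5.07 ± 0.90 (edgeR adjusted p = 0.0184) and Dnali1 at 6.24 ± 1.12 (SE, edgeR adjusted p = 0.0206), and 14 adjusted over the list alone (median 2.08; camera adjusted p = 2.22e-07, adjusted p = 0.131 with an estimated correlation). Dnali1 overlaps Gnl2 on the other strand and Hydin overlaps Gm26832, so both are uncertain. The replicate block kept the calls of Rsph1, Hydin, Ccdc40, Dnaaf1, Wdr63 and Dnali1 and ended those of Cfap44 (edgeR adjusted p = 0.0593) and Kif9 (edgeR adjusted p = 0.0787); with it 7, 4, 4 and 2 members of the 4 lists were called higher. Without IP 1, 35, 18, 16 and 12 members were called, without IP 3 20, 5, 4 and 3, and without IP 4 or any 1 Input at most 1 per list.

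Most genes of a further list of ependymal markers were higher too. Of 20 such markers 15 were higher, with a median log2 fold of 4.93 (19 adjusted over the list alone; camera adjusted p = 4.66e-12, adjusted p = 0.251 with an estimated correlation). Ccdc153 rose from 5.31 ± 2.10 to 391 ± 303 CPM (log2 fold 6.20 ± 0.78 SE, edgeR adjusted p = 0.0108), and Mia, a secreted protein gene, from 1.57 ± 0.57 to 33.4 ± 24.9 CPM (log2 fold 4.41 ± 0.63 SE, edgeR adjusted p = 0.0117). Mia overlaps the model Gm21983 on the same strand and is uncertain. With the block both lost the call (edgeR adjusted p = 0.0606 for each), and 6 members of the list were called. Without IP 1, 19 members were called, without IP 3 13, without Input 1 or Input 2 2, and without IP 4 1. The list's median log2 ratio to the mean Input was 1.89 in IP 1, 5.78 in IP 3 and 5.15 in IP 4.

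**Figure D2:**
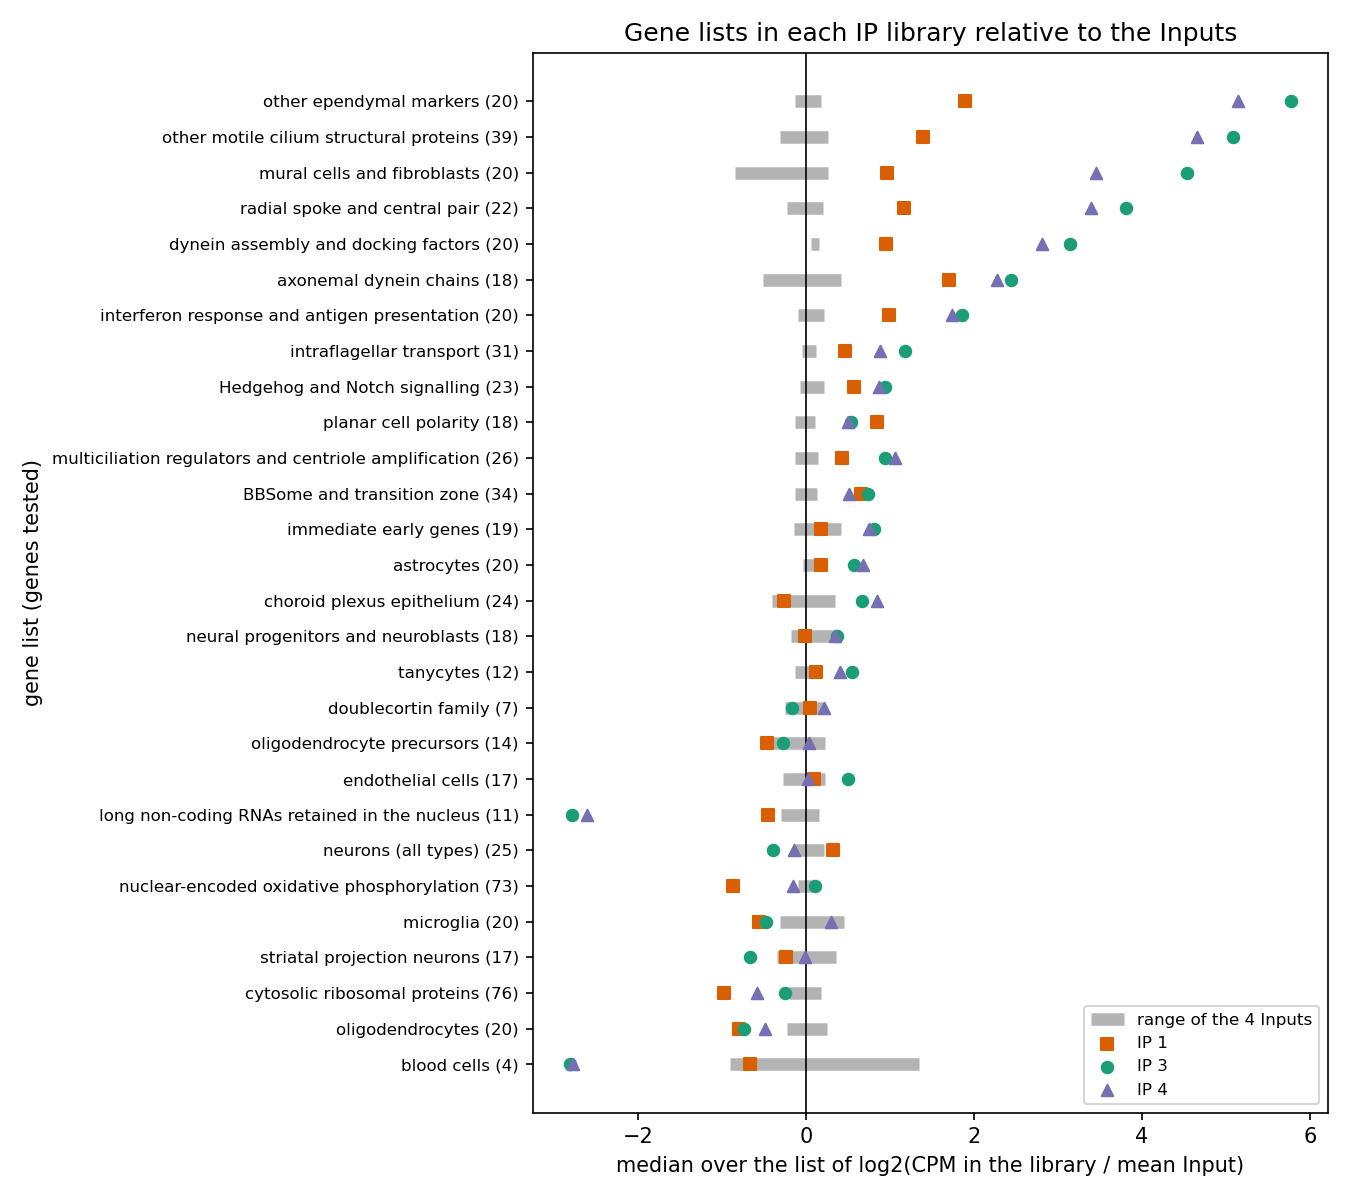
Median log2 ratio of each gene list to the mean Input, in each IP library (coloured symbols), with the range of the 4 Inputs as a grey bar. The ependymal markers reach 1.89 in IP 1, 5.78 in IP 3 and 5.15 in IP 4, and the mural cell and fibroblast genes 0.97, 4.54 and 3.45; the lncRNAs retained in the nucleus are at -0.46, -2.79 and -2.62.

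Some regulators and shared parts of cilia were higher too. Of 26 regulators of multiciliation and centriole amplification 7 were higher, among them Trp73, a transcription factor of multiciliated cells (log2 fold 4.36 ± 0.72 SE, edgeR adjusted p = 0.0147), and Foxj1. The list had a median log2 fold of 0.63 and 11 members passing adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.251 with an estimated correlation). Trp73 lost its call with the block (edgeR adjusted p = 0.0606) and overlaps the antisense gene Trp73os. Of 31 intraflagellar transport genes 3 were higher, including Ift43 (2.73 ± 0.59 SE, edgeR adjusted p = 0.0318) and Cluap1 (1.02 ± 0.25 SE, edgeR adjusted p = 0.0435); 30 of the 31 had a positive fold (median 0.80; 10 adjusted over the list alone; camera adjusted p = 5.25e-07, adjusted p = 0.131 with an estimated correlation). Of 34 BBSome and transition zone genes 5 were higher, led by Tmem107 (3.80 ± 0.66 SE, edgeR adjusted p = 0.0188), with a median of 0.58 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000118, adjusted p = 0.224 with an estimated correlation). Of 18 planar cell polarity genes 2 were higher, Ptk7 (3.53 ± 0.59 SE, edgeR adjusted p = 0.0147) and Celsr1 (2.36 ± 0.45 SE, edgeR adjusted p = 0.0207), with a median of 0.70 (6 adjusted over the list alone; camera adjusted p = 0.00123, adjusted p = 0.131 with an estimated correlation). With the block Ift43 (edgeR adjusted p = 0.0742), Cluap1 (0.211), Tmem107 (0.104), Ptk7 (0.127) and Celsr1 (0.103) were no longer called. Without IP 1 the members called higher in these 4 lists numbered 11, 19, 11 and 7, and without IP 4 or any 1 Input at most 1 in each.

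The doublecortin family, to which Dcdc2a belongs, did not move together. Of 7 measured members Dcx, a marker of young neurons, fell (log2 fold -0.77 ± 0.19 SE, edgeR adjusted p = 0.0423) and Dcdc5 had a log2 fold of 4.61 ± 1.19 (SE, edgeR adjusted p = 0.052). Adjusted over the list alone 2 were higher and 2 lower. The median (0.20) and mean (0.74) were positive while camera gave the direction as down (adjusted p = 0.980, and 0.981 with an estimated correlation); with total counts as the scaling camera's direction was up (as it was with the block, without a low-count filter, with the lower-numbered libraries alone, and without IP 1, IP 3, Input 3 or Input 4), Dcdc5 passed (edgeR adjusted p = 0.0494) and Dcx did not (edgeR adjusted p = 0.0572). Dcx lost its call with the block (edgeR adjusted p = 0.176) and without IP 3, IP 4 or any 1 Input; without IP 1 Dcdc5 passed (edgeR adjusted p = 0.0134). Dcdc5 is annotated as a pseudogene overlapping Dnajc24 and is uncertain.

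Some genes of other cells around the ventricle rose too. Of 20 genes of mural cells and fibroblasts, the cells on the outside of vessels and in the meninges, 10 were higher with a median log2 fold of 3.40 (17 adjusted over the list alone; camera adjusted p = 8.90e-09, adjusted p = 0.259 with an estimated correlation). Vtn, a pericyte gene, rose from 5.03 ± 2.02 to 115 ± 114 CPM (log2 fold 4.51 ± 0.78 SE, edgeR adjusted p = 0.0185), and the collagen gene Col1a1 by a log2 fold of 4.02 ± 0.80 (SE, edgeR adjusted p = 0.0231). In Col1a1 the IP 1 level of 2.78 CPM was close to the 2.43 CPM of Input 1. The list's median log2 ratio to the mean Input was 0.97 in IP 1, 4.54 in IP 3 and 3.45 in IP 4. With the block Vtn (edgeR adjusted p = 0.0791) and Col1a1 (edgeR adjusted p = 0.229) were not called, and 1 member of the list was. Of 17 endothelial genes, from the inner wall of the same vessels, 2 were higher, Cdh5 (3.66 ± 0.84 SE, edgeR adjusted p = 0.0356) and Slc2a1 (1.63 ± 0.39 SE, edgeR adjusted p = 0.0396), and 3 adjusted over the list alone. The endothelial median was -0.01, the mean 0.18 and camera's direction up (adjusted p = 0.911, and 0.938 with an estimated correlation); the median was 0.05 with total counts, and camera's direction was down without IP 3, IP 4 or Input 4 (adjusted p = 0.869, 0.893 and 0.787) and with the lower-numbered libraries alone (0.456). Cdh5 (0.244) and Slc2a1 (0.213) lost the edgeR call with the block (adjusted p in brackets). Without IP 1, 16 mural and fibroblast and 4 endothelial members were called, and without IP 3 2 of the mural and fibroblast list and 0 of the endothelial. Without IP 4 or any 1 Input at most 1 of either list was called.

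Of 24 choroid plexus genes 3 were higher, with Calml4 at 4.89 ± 0.73 (SE, edgeR adjusted p = 0.0136) and Slc13a4, a sulfate transporter, at 2.35 ± 0.46 (SE, edgeR adjusted p = 0.0231), and 3 adjusted over the list alone. The list's median was 0.49 (camera adjusted p = 0.0204, adjusted p = 0.564 with an estimated correlation). Of 20 astrocyte genes 3 were higher (3 adjusted over the list alone; median 0.50; camera adjusted p = 0.032, adjusted p = 0.323 with an estimated correlation), among them Mlc1 (1.71 ± 0.35 SE, edgeR adjusted p = 0.0249) and the connexin gene Gjb2 (3.37 ± 0.72 SE, edgeR adjusted p = 0.033). Both lists lost the camera call with the block (adjusted p = 0.0563 and 0.0525), without IP 3 (0.106 and 0.0742), without IP 4 (0.139 and 0.0915) and without Input 2 (0.0576 for each). They also lost it with the lower-numbered libraries alone (0.0579 and 0.0985) and with the block and the GC and length offsets (0.0554 and 0.0891), and the astrocyte list with the offsets alone (0.0535). With the block Calml4 (0.0806), Slc13a4 (0.0887) and Mlc1 (0.145) were not called by edgeR (adjusted p in brackets) and Gjb2 was (0.0443). Of 12 tanycyte genes 1 was higher, the sodium channel gene Scn7a (2.48 ± 0.58 SE, edgeR adjusted p = 0.0364, and 0.205 with the block), and Dio2 had a log2 fold of -1.20 ± 0.37 (SE, edgeR adjusted p = 0.0853). Adjusted over the list alone 1 was higher and 1 lower (median 0.32; camera adjusted p = 0.438, and 0.616 with an estimated correlation). None of 18 genes of progenitors and neuroblasts passed over all genes or adjusted over the list alone (median 0.34; camera adjusted p = 0.252, and 0.601 with an estimated correlation), including Nes at 3.78 ± 1.27 (SE, edgeR adjusted p = 0.112) and Sox11 at -0.57 ± 0.20 (SE, edgeR adjusted p = 0.121). Of the progenitor genes edgeR had 1 higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 1 and 1, and voom 0. Without IP 1, 7 choroid plexus and 9 astrocyte genes were called higher, and Nes, Sox11 and Dio2 passed (edgeR adjusted p = 0.0142, 0.0317 and 0.0156).

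Interferon and signalling genes were higher as lists. Of 20 genes of the interferon response and antigen presentation 3 were higher and all 20 had a positive fold (median 1.35; 6 adjusted over the list alone; camera adjusted p = 2.13e-06, adjusted p = 0.242 with an estimated correlation). Oasl2 rose by a log2 fold of 4.07 ± 0.73 (SE, edgeR adjusted p = 0.0185, and 0.00952 with the block) and Ifitm3 by 4.18 ± 0.76 (SE, edgeR adjusted p = 0.0208, and 0.166 with the block). Of 23 genes of Hedgehog and Notch signalling 3 were higher, including Notch2 (1.38 ± 0.31 SE, edgeR adjusted p = 0.0341) and Gli2 (1.71 ± 0.40 SE, edgeR adjusted p = 0.038), with a median of 0.77 (8 adjusted over the list alone; camera adjusted p = 0.00133, adjusted p = 0.169 with an estimated correlation). With the block Notch2 (0.182) and Gli2 (0.173) were not called by edgeR (adjusted p in brackets). Of 19 immediate early genes Nr4a1 rose (0.87 ± 0.22 SE, edgeR adjusted p = 0.0483) and Egr3 fell (-0.78 ± 0.17 SE, edgeR adjusted p = 0.033), and 2 were higher and 1 lower adjusted over the list alone. The list was not called (median 0.51; camera adjusted p = 0.0999, and 0.564 with an estimated correlation), but was with the block (camera adjusted p = 0.0197) and without Input 2 (0.0442). Nr4a1 (0.167) and Egr3 (0.184) lost their calls with the block (edgeR adjusted p in brackets), and Nr4a1 with total counts (edgeR adjusted p = 0.0518) and upper quartile factors (0.0539). Without IP 1 the members called higher in the 3 lists numbered 9, 8 and 6, and without IP 4 or any 1 Input none of these 6 named genes was called. Without IP 3, Oasl2 and Ifitm3 kept the call (edgeR adjusted p = 0.0372 and 0.0439) and the other 4 did not. Notch2 overlaps the model Gm42820 and is uncertain.

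Of 20 genes of oligodendrocytes, the myelin-forming cells, 3 fell, 17 were not called and 4 had a positive fold; those that fell include Gjc3 (-1.28 ± 0.20 SE, edgeR adjusted p = 0.0129) and Mobp (-1.17 ± 0.28 SE, edgeR adjusted p = 0.0406). The median was -0.62, and adjusted over the list alone 8 were lower and 1 higher (camera adjusted p = 0.00121, adjusted p = 0.328 with an estimated correlation). With the block 0 members of the list were called by edgeR (adjusted p = 0.0606 for Gjc3 and 0.107 for Mobp), while camera called the list (adjusted p = 0.000779), and without IP 1 8 members were called lower. Without IP 4 or any 1 Input no member of the oligodendrocyte list was called by edgeR, while camera called the list in each of these fits. Of 14 genes of their precursors none passed over all genes or adjusted over the list alone, with Olig1 at -0.66 ± 0.21 (SE, edgeR adjusted p = 0.0956) and Cspg4 at 1.59 ± 0.51 (SE, edgeR adjusted p = 0.0968). That list's median was 1.18e-05, its mean -0.000585 and camera's direction down (adjusted p = 0.461, and 0.725 with an estimated correlation); the median was -0.40 with the block, -0.38 with the block and the GC and length offsets, -0.21 with voom and 0.12 without IP 3. Of the precursor genes edgeR had 1 higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 1 and 1, and voom 0. Of 25 genes of neurons Map2 alone was called and fell, from 774 ± 36.4 to 361 ± 46.4 CPM (log2 fold -1.10 ± 0.17 SE, edgeR adjusted p = 0.0129, and 0.0858 with the block), while Grin1 had a log2 fold of 0.70 ± 0.21 (SE, edgeR adjusted p = 0.0835). Map2, Grin1, Mobp and Olig1 overlap other models and are uncertain. Snap25, chosen after its value was seen, had 5629 ± 823 CPM in IP and 7864 ± 965 in Input (log2 fold -0.48 ± 0.18 SE, edgeR adjusted p = 0.15). Without IP 1 Cspg4, Grin1 and Snap25 passed (edgeR adjusted p = 0.024, 0.00622 and 0.0215). The neuron list was not called (median -0.07, mean 0.00205, camera's direction down; 1 lower adjusted over the list alone; camera adjusted p = 0.383, and 0.812 with an estimated correlation) but was lower without IP 1 (camera adjusted p = 0.0236), and without IP 3 camera's direction was up (adjusted p = 0.839).

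Of 17 genes of striatal projection neurons none passed over all genes or adjusted over the list alone, with Tac1 at -0.73 ± 0.24 (SE, edgeR adjusted p = 0.105) and Pdyn at 10.2 ± 3.24 CPM in IP and 20.5 ± 4.96 in Input (edgeR adjusted p = 0.125). The list's median of -0.29 was called by camera (adjusted p = 0.043, adjusted p = 0.601 with an estimated correlation), but not without IP 1 (0.0533), IP 3 (0.517), Input 3 (0.0601) or Input 4 (0.184). Of 20 microglial genes none passed over all genes or adjusted over the list alone (median -0.22; camera adjusted p = 0.243, and 0.725 with an estimated correlation), including Fcer1g at -1.39 ± 0.45 (SE, edgeR adjusted p = 0.098) and Csf1r at 0.87 ± 0.33 (SE, edgeR adjusted p = 0.149). Camera called it lower with the block (adjusted p = 0.0426), without IP 4 (0.0189) and without Input 2 (0.0477). At an unadjusted p under 0.05 edgeR had 1 higher and 3 lower striatal genes and 1 higher and 2 lower microglial genes. DESeq2 called 2 striatal genes and 1 microglial gene lower, and voom 0 of either. Of 4 blood genes none passed over all genes and 2 were lower adjusted over the list alone (median -1.98; camera adjusted p = 0.0126, adjusted p = 0.344 with an estimated correlation). The haemoglobin genes Hbb-b2 and Hbb-bs had log2 folds of -2.40 ± 0.83 and -2.01 ± 0.72 (SE, edgeR adjusted p = 0.121 and 0.135) and are near-identical copies, so their counts are uncertain. Within lanes their log2 ratios were -2.62 to -2.32 and -1.999 to -1.985. They were not called with the block (edgeR adjusted p = 0.127 and 0.061) and passed without IP 1 (0.00561 and 0.00322), as did Tac1 (0.0171) and Pdyn (0.0318). Camera called the blood list with the block (adjusted p = 0.000265). Of the blood genes 2 were lower by edgeR at an unadjusted p under 0.05 and by DESeq2, and 0 by voom.

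The genes with the largest fall under the naming rule were Bnc2, Tbrg3, Sptssb, Nrsn1, Mccc1os, Kcnq1ot1, Ctxn3, Bend6, Khdrbs2 and Zdhhc2, with log2 folds from -4.46 (Bnc2) to -2.07 (Zdhhc2). Nrsn1, a neuronal membrane protein gene (ENSMUSG00000048978.14, chromosome 13, 25252040 to 25270502, minus strand), fell from 379 ± 31.3 to 53.7 ± 12.4 CPM (log2 fold -2.82 ± 0.22 SE, edgeR adjusted p = 0.000269). Bend6 fell from 398 ± 32.2 to 80.1 ± 6.85 CPM (log2 fold -2.31 ± 0.18 SE, edgeR adjusted p = 0.000275). Both kept the call without any 1 library and with the block (edgeR adjusted p = 0.00488 and 0.00999). Bnc2 (0.023), Kcnq1ot1 (0.0443) and Zdhhc2 (0.0344) also kept it with the block, and Tbrg3 (0.0569), Sptssb (0.0912), Mccc1os (0.137), Ctxn3 (0.0606) and Khdrbs2 (0.135) did not (edgeR adjusted p in brackets). Mccc1os, Kcnq1ot1 and Zdhhc2 overlap Mccc1, Kcnq1 and Cnot7 and are uncertain. Of the models named by a sequence accession 16 were called higher and 41 lower, and all 8 models that fell at least 16-fold with a mean CPM of at least 100 carried such names. AK140265, chosen after its values were seen, fell from 53023 ± 12352 to 1620 ± 476 CPM (log2 fold -5.03 ± 0.31 SE, edgeR adjusted p = 0.000105) and DQ539915 by -6.18 ± 0.32 (SE, edgeR adjusted p = 4.03e-05). The tables used here do not pair these models with genes.

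Nuclear RNA and ribosomal protein genes were lower as lists, and mitochondrial protein genes in some fits. Of 11 lncRNAs retained in the nucleus Kcnq1ot1 fell (-2.54 ± 0.34 SE, edgeR adjusted p = 0.0105), and 1 was lower adjusted over the list alone. The list's median was -0.04 and its mean -0.44 (camera adjusted p = 0.00667, adjusted p = 0.251 with an estimated correlation), and 4 of the 11 had a positive fold. Neat1 had 16.9 CPM in IP 1 against 1.41 and 1.31 in IP 3 and IP 4 (log2 fold -2.47 ± 0.89 SE, edgeR adjusted p = 0.141). Without IP 1 7 of the 11 were called lower, Neat1 among them (edgeR adjusted p = 2.28e-06), and the median was -2.75. On all libraries the median was -2.34 with the block, -2.19 with the block and the GC and length offsets and -1.71 with voom. Of 76 cytosolic ribosomal protein genes 3 fell, including Rps15a (-1.29 ± 0.25 SE, edgeR adjusted p = 0.0219) and Rplp1 (-1.17 ± 0.28 SE, edgeR adjusted p = 0.0389), with a median of -0.56 (3 adjusted over the list alone; camera adjusted p = 5.62e-09, adjusted p = 0.259 with an estimated correlation). These genes have many near-identical copies and are uncertain; with the block Rps15a (0.0911) and Rplp1 (0.086) were not called by edgeR (adjusted p in brackets). Without IP 3 8 ribosomal protein genes were lower, and without IP 4 or any 1 Input none passed. The ribosomal list's median log2 ratio to the mean Input was -0.98 in IP 1, -0.26 in IP 3 and -0.59 in IP 4. In the Inputs it ranged from -0.21 to 0.18. Of 73 nuclear genes of oxidative phosphorylation none passed over all genes or adjusted over the list alone (median -0.14; camera adjusted p = 0.0251, adjusted p = 0.644 with an estimated correlation), with Atp5g1 at -1.15 ± 0.30 (SE, edgeR adjusted p = 0.0522) and Cox6a1 at -1.01 ± 0.29 (SE, edgeR adjusted p = 0.0675). Of these edgeR had 1 higher and 8 lower at an unadjusted p under 0.05, DESeq2 called 5 lower and voom 0. The camera call of that list was lost without IP 1 (adjusted p = 0.714), with the GC and length offsets (0.0526) and with the lower-numbered libraries alone (0.0511). Without IP 1 Atp5g1 and Cox6a1 passed (edgeR adjusted p = 0.0249 and 0.00565), and without IP 3 Cox6a1 (0.0303). The list's median log2 ratio to the mean Input was -0.87 in IP 1, 0.11 in IP 3 and -0.16 in IP 4.

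IP 1 lay nearer to the Inputs than the other IP libraries did. Its log2 CPM values correlated with those of the Inputs at 0.891 to 0.895 across genes, against 0.811 to 0.835 for IP 3 and IP 4, and with IP 3 at 0.823 and IP 4 at 0.852 (genes are not independent replicates). The lncRNAs Meg3 and Malat1, chosen after their values were seen, had 13673 and 17609 CPM in IP 1, 230 and 1257 in IP 3, and 310 and 1106 in IP 4. In the Inputs Meg3 ranged from 2647 to 3647 and Malat1 from 17572 to 31289 CPM. The accession-named model AK140265 had 2153 CPM in IP 1, near the 1469 and 1238 CPM of IP 3 and IP 4. The ratio to Input also rose with transcript length in IP 1, with a Spearman correlation across 11600 genes of 0.237, against -0.128 in IP 3 and -0.0436 in IP 4. Reads in more than 1 gene made up 1.91%, 2.01% and 1.51% of the lines in IP 1, IP 3 and IP 4 and 9.33% to 12.9% in the Inputs. By contrast, reads in no gene made up 18.4% in IP 1, near the 15.2% to 18.2% of the Inputs, against 8.85% in IP 3 and 8.15% in IP 4.

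**Figure D3:**
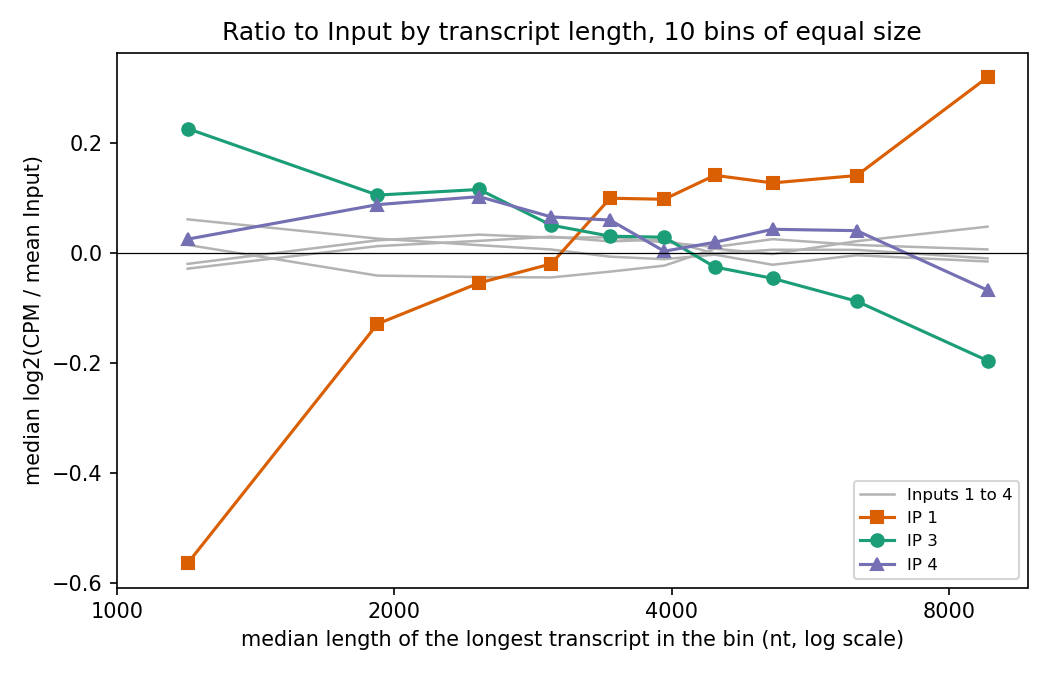
Median log2 ratio to the mean Input in 10 bins of 1160 genes by the length of the longest annotated transcript, for each IP library (coloured) and each Input (grey). IP 1 goes from -0.56 in the bin of the shortest transcripts to 0.32 in that of the longest, while IP 3 goes from 0.23 to -0.20.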

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

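In this part, the tests of carry-over, of the number of ependymal cells, of whole vessels, of the length and GC trend in the mural list and of the gene lists across splits were chosen after the results were seen.

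IP 1 held a smaller excess of ependymal and cilium genes than the other IP libraries: over 119 genes the median log2 ratio to the mean Input was 1.30 in IP 1, 4.03 in IP 3 and 3.67 in IP 4. A length and GC trend of IP 1 is argued against, since with offsets for both the gap was 2.47 log2 units (2.55 without them), and, if IP 1 and Input 1 come from the same tissue, which is not labelled, so is a smaller number of ependymal cells in it: the median log2 ratio of these genes in Input 1 to the other Inputs was -0.065 (SD of the same median over the other Inputs 0.153). Carry-over of Input RNA with all libraries prepared alike was tested on the genes called lower without IP 1. Of these 1724 genes, the 1721 also tested with IP 1 included had a median log2 ratio of -0.49 in IP 1 (-1.21 in IP 3 and -1.22 in IP 4). It lay under the -0.21 that the share of the excess in IP 1 (upper quartile 13.8%) allows, with an SD over the Inputs of 0.026. The ratios had no offsets for the length trend of IP 1, and the genes were chosen with the same Inputs that form the ratio. Both can lower the ratio, so the test cannot decide. Carry-over beside a preparation step that differs between all IP and all Input libraries cannot be told apart from a weaker purification. Such a step would go with the groups, and the labels name none. The test took 53 genes with at least 10 CPM in the mean Input, at least 8-fold lower in both IP 3 and IP 4. Of these, 22.6% were more than 4-fold lower in IP 1, against at most 1.89% in any Input. Without such a step, falls of this size argue against IP 1 being mostly Input RNA, for these 12 genes. But 11 of them were accession-named models, and whether a preparation step lowered those was not tested. Of the 15 other genes 1 was more than 4-fold lower in IP 1 (6.67%). Of the 53, 28.3, 20.8, 11.3, 5.66 and 0% exceeded every Input in IP 1 by more than 0, 0.5, 1, 1.5 and 2 log2 units, against at most 60.4, 15.1, 1.89, 1.89 and 0% in 1 Input over the others, so RNA of another composition stays open.

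Genes of mural cells and fibroblasts were higher in IP although the tag is driven by Dcdc2a. For the pooled list, whole vessels caught with the beads are argued against. The upper quartile of the endothelial list (log2 fold 1.03) lay under the lower quartile of the mural and fibroblast list (2.29). That list also holds fibroblast genes, and the quartile was not taken over the mural genes alone. A length and GC trend is argued against too, as the list's median was 3.36 with both offsets. Split by cell type after the values were seen, 3 of 11 mural genes were called (median 2.56) and 7 of 9 fibroblast genes (median 3.68). Expression of the tag in some of these cells may account for the rise and was not tested.

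Among the 35 splits of the 7 libraries into 3 and 4, 1 gave as many genes higher, the real one (633, highest other 0), and 1 as many lower (376, highest other 1). For both counts this share is under the 0.05 set beforehand. Every other split puts IP and Input libraries together in a group, which widens the spread within it. Low counts in those splits therefore cannot exclude chance. The 8 splits that part 3 pairs are too few for a share under 0.05 (633 and 376, highest other 0 and 1); the other 7 mix IP and Input libraries. Chance cannot be excluded for the counts of gene lists: 3 splits called as many lists higher (14, highest other 15) and 13 as many lower (6, highest other 14). The splits with 14 and 15 lists higher keep IP 3 and IP 4 together with Input 3 or Input 4. A count of lists in either direction was run first and gave 20, with 19 as the highest other split and 1 split of 35 as large; it was replaced because the 2 directions had been set as separate results.

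In 10 of 124 groups of 4 Input values, 1 library lay far from the others, where chance gives about 1 in 20. Of these 4 are Y-linked genes in Input 2, which amount to 1 difference, and the other 6 of 120 are no more than that chance share. Lrrc18 had 1.04 CPM in Input 3 (0.0981 to 0.147 in the others), and Ptk7 3.46 in Input 1 (1.12 to 1.33). Nes had 1.62 CPM in Input 4 (0.0491 to 0.137 in the others), and Mlc1 23.4 in Input 3 (33.0 to 33.5). Vtn had 8.02 CPM in Input 2 (3.61 to 4.29 in the others), and Igf2 397 in Input 1 (175 to 211). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 59.0, 16.3, 16.1 and 24.1 CPM in Input 2, and at most 0.0273 in any other Input and 0.16 in any IP library. Xist, expressed from the inactive X chromosome, had 47.2 to 69.0 CPM in the other Inputs and less in Input 2 (179 counts). By these genes Input 2 is of another sex than the other 6 libraries, so the comparison of IP with Input includes 1 Input of another sex. Without Input 2, 12 genes were higher and 24 lower. This drop is not particular to Input 2: the counts were 21 and 30 without Input 1, 4 and 16 without Input 3, and 4 and 19 without Input 4.

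Reads aligned to more than 1 place, which were not used for genes, made up 29.6% of the lines in IP 3 and 39.3% in IP 4, against 20.9% to 21.2% in the Inputs and 19.8% in IP 1.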

How the results depend on the processing

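The fits without IP 1 that add a block or an estimated correlation, and the fit without robust moderation, were chosen after the data were examined. The counts of genes higher (633) and lower (376) stayed within 1.5 times under the other scalings, both other low-count filters, the GC and length offsets without a block, and the fit without robust moderation. They were 1582 and 1149 with DESeq2, 75 and 189 with limma-voom, and 227 and 68 with glmTreat against a fold of 1.5. They were 280 and 188 with the library number series as a covariate. With the lower-numbered libraries alone, edgeR called 0 higher and 10 lower (2365 genes at an unadjusted p under 0.05), with fewer libraries. The replicate block gave 96 and 33, the block with GC and length offsets 148 and 53, and the block without IP 1 2082 and 1704. Leaving out 1 library gave 4 (Input 3 or 4) to 2259 (IP 1) higher and 16 (Input 3) to 1724 (IP 1) lower. The cause was not tested. At an unadjusted p under 0.001 the main test had 550 genes, and 247 to 282 without any 1 Input.

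Of 60 called genes followed across the settings, the block kept 21, voom 15, DESeq2 60 and glmTreat 40; leaving out IP 1 kept 60, IP 3 42, IP 4 7, and Inputs 1 to 4 kept 10, 8, 5 and 5. Across the genes chosen for naming and the settings, without the counts above, 1285 results kept their direction and side of the threshold, 512 lost the call, 60 gained it and 6 turned, all of them Rpl10a, which was not called. Its log2 fold was -0.038 with the block, -0.0092 with the block and GC and length offsets, -0.17 with the block without IP 1, and from -0.17 (without IP 4) to 0.41 (without Input 4) leaving out 1 library. Camera's direction also turned in some fits for the doublecortin, endothelial and neuron lists, none of them called there. Among the genes named in the text and the gene lists, the block changed no call beyond those given beside the results.

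With an estimated correlation camera called 0 lists higher and 0 lower (5 and 0 at an unadjusted p under 0.05), and without IP 1 4 higher and 0 lower (11 and 1 unadjusted). Fry called 3 lists lower. At this depth 3 counts correspond to 0.0585 to 0.0819 CPM per library, so Input levels of genes near that, such as Crygn and Dthd1, carry a large counting error.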

Other observations

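The comparison of Meg3, Snhg11, Miat and Rn45s between libraries was chosen after the values were seen. The lncRNA Meg3 had 13673 CPM in IP 1, 230 in IP 3 and 310 in IP 4, and 2647 to 3647 in the Inputs. Snhg11 had 5749 CPM in IP 1, 166 in IP 3 and 125 in IP 4, and Miat 498, 15.5 and 11.1. Both were also above every Input in IP 1 (Snhg11 1376 to 2013, Miat 163 to 196). Rn45s, the ribosomal RNA precursor, had 77885 CPM in IP 4 and 14487 in Input 4, and 2808 to 9284 in the other libraries.

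The insulin-like growth factor gene Igf2, chosen after its values were seen, had 224, 1809 and 940 CPM in IP 1, IP 3 and IP 4 and 175 to 397 in the Inputs (edgeR adjusted p = 0.0774). Without IP 1 it passed (log2 fold 2.47, edgeR adjusted p = 0.00133), and over the other fits that left out 1 library its edgeR adjusted p ranged from 0.103 to 0.231.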
